A study of Mus musculus with 11 samples.

How the data were processed

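The study measured DNA methylation by MeDIP-seq, in which an antibody captures methylated DNA fragments that are then sequenced. The tissue was the suprachiasmatic nucleus (SCN), the master circadian clock in the hypothalamus, of wild-type C57BL/6 mice kept for 6 weeks on light-dark cycles of 22, 24 or 26 h and then for 3 days in darkness. Brains were taken at circadian time 4, a slice of about 250 µm was cut through the SCN and parted into ventral and dorsal pieces, and the DNA was sonicated to fragments of about 300 bp. The labels give 11 samples in 6 groups, with 2 samples in each group except the dorsal 24 h group, which has 1, although the series entry speaks of duplicates.

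The submitters' processing notes name BWA and the mouse genome build mm9, without a BWA version. The authors deposited 4 lists of selected windows, each comparing the 24 h cycle with the 22 h or the 26 h cycle in the ventral or the dorsal part. Every listed window is 500 bp long and lies on a fixed grid. Each list has 1 column of values per cycle length, and its columns of means repeat these values, so the files show no replicates. How duplicate samples were combined is not stated.

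Per the file headers, each cycle length has a deposited column named counts, but its values are a score and not reads: within a column they are a rescaled function of the reads that keeps their order. The authors' second kind of column gives RPKM, that is reads scaled to the length of the window and the reads of the column. The authors' log2 fold change, per the file headers, comes from edgeR and is the 24 h column over the other. The p-value of each window, per the file headers, is also from edgeR and is unadjusted; with 1 column per cycle length it compares columns, not groups of mice. The authors' tables also name the nearest gene and give the distance in bp to its transcription start site. A window can lie far from the gene it is named after, such as 1576260 bp for a window nearest Cdh11. The authors' criteria for the lists are not stated, and windows outside the lists were not analysed here.

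Reads per window were recovered from the RPKM values, because all windows have the same listed length and 1 read is therefore worth a constant step in each column. All low RPKM values were whole multiples of that step within 0.01 RPKM. The step gave the depth of each column. Ratios of RPKM between columns carry exact 95% intervals from the binomial distribution of the recovered reads (Clopper-Pearson). Where a column held 0 reads, the fold was computed against a floor of 3 reads in that column and is given as a lower bound; the exact 95% limit, which also covers counting error in the other column, lies lower. Intervals, floors and p-values cover counting error only: reads without molecular identifiers are not independent molecules, and the spread between mice cannot be seen. Unlisted windows were not analysed here, so no count adjusted over the list alone could be given for the gene lists.

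Windows were annotated with the mm9 genome and GENCODE M1, with windows within 1000 bp of the start site of any transcript called promoter. Such a window can lie far from the start site that the authors give for the gene. Sequence content was examined after the values were seen. For each listed window and for 2000 random windows, CpG dinucleotides and GC content were counted, and each 31-base word was searched in the whole genome. A window was called mostly unique when at least 50% of its words occurred once and it did not match the mitochondrial chromosome. Features of LINE-1 retrotransposons were a reading frame of at least 600 codons within 8000 bp that holds the reverse transcriptase motif FADD, and tandem units as in mouse LINE-1 promoters, counted where at least 30% of the window's 15-base words recurred 190 to 225 bp away and not within 100 bp. The feature of LTR retrotransposons was a frame of that length with the motif YXDD. Short tandem repeats were counted where at least 30% of these words recurred within 100 bp. Windows were aligned to the mitochondrial chromosome with BLAST 2.17.0, and a match meant at least 80% of the window at 90% identity or more. A repeat annotation was not used here. The scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, Biopython 1.88 and matplotlib 3.10.9.

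Before the data were examined, 16 gene lists, the rule for named genes and most of the settings below were fixed. The lists were circadian clock genes, SCN neuropeptides and their receptors, GABA signalling and chloride transport, glutamate receptors and transporters, voltage-gated and pacemaker ion channels, light input and second-messenger signalling, DNA methylation machinery, axon guidance, synaptic and neural cell adhesion, SCN and hypothalamic developmental transcription factors, imprinted genes, and markers of neurons, astrocytes, oligodendrocytes, microglia and vascular or meningeal cells. Named in the text were the 10 largest fold changes in each direction of a list, windows near members of the gene lists (up to 15 per gene list), and genes found in 3 or 4 of the authors' lists or in both lists of a part (up to 10). Predicted genes were named only among the 3 largest changes. Any gene named outside this rule is marked where it appears.

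Members of each gene list among the genes named by the authors were counted against all GENCODE genes with a one-sided Fisher exact test, with Benjamini-Hochberg adjustment over 64 tests (16 lists in 4 comparisons). Shared windows were those with at least 1 bp in common, and where the lists have no column in common, shared genes were tested with a one-sided Fisher exact test and the direction of shared windows with a two-sided exact binomial test. The chromosomes of the windows were compared with chromosome lengths by a permutation test with 100000 draws. Shares of windows carry exact 95% intervals (Clopper-Pearson). Sequence features were compared with two-sided Fisher exact tests adjusted over 108 tests.

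The alternatives were a p limit 10 times stricter, a fold change of at least the list's median, merged neighbouring windows (within 1000 bp), no sex chromosomes, protein-coding genes only, windows inside the gene or its promoter, random genes of matched length (10000 draws), and wider distances for shared windows. Chosen after seeing the data were a p limit of 1e-05 in every list, mostly unique windows only, a two-sided exact binomial test of the recovered reads scaled to column depth or with a constant approximation of the authors' scaling (the list's median difference between their log2 fold change and the log2 ratio of RPKM), direction taken from RPKM, random windows named after the nearest start site, and merged windows for the chromosome test. The scaled binomial test and the Fisher test were tested on simulated data: among windows simulated at the rates of the ventral 24 h against 22 h list with 200 windows changed 4-fold, 94% were called at the list's limit and 0 of 612 unchanged windows were. For 2-fold changes the share called in that list was 12.5%. The bar for an effect of depth in a single list was changed after the values were seen: at first under 50% of lower windows passing the scaled test was enough, and later under 50% also had to keep an interval below 1, which left depth open in ventral 24 h against 26 h and dorsal 24 h against 22 h. The test for loss of multi-copy reads took 4 forms after the values were seen. The first and the second (CpGs of random multi-copy windows, and the share of mostly unique windows) were dropped as void, the third (retrotransposon features among mostly unique windows) was kept, and the fourth used windows with at least 90% unique words. The third was at first read as evidence against such a loss and is now read as open, because its windows are multi-copy in part. The test of CpG-dense capture first used all mostly unique windows (permutation p = 0.0016) and then only those without retrotransposon features. Analyses by replicate were left out because the files hold none.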

Results

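The data comprised 4 lists of 500-bp windows in which the authors found different amounts of captured methylated DNA between mice on 24 h cycles and mice on 22 h or 26 h cycles. The question, as the title and labels give it, concerns plasticity of the circadian clock: whether the length of the day leaves a mark on DNA methylation in the SCN. Ventral and dorsal parts were listed apart. The depth recovered from the ventral columns was about 5230000 reads at 24 h, 8170000 at 22 h and 9430000 at 26 h. The dorsal columns held 4580000, 5720000 and 5770000 reads in that order. The 24 h column was therefore the shallowest in both parts. Each group appeared as 1 column, so no difference given here could be set against the spread between mice, and the labels give 1 sample for the dorsal 24 h group, although the series entry speaks of duplicates.

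The lists differed in size. They held 812 windows for ventral 24 h against 22 h, 217 for ventral 24 h against 26 h, 131 for dorsal 24 h against 22 h and 79 for dorsal 24 h against 26 h. Most windows were lower at 24 h in every list as the authors scaled it. The share higher at 24 h was 24.3% (95% interval 21.4 to 27.4) in the first list (but 86.1% among its mostly unique windows, 111 higher and 18 lower), 26.7% (21.0 to 33.1) in the second (but 44.9% of its 78 regions with neighbouring windows merged, 35 higher and 43 lower), 3.05% (0.838 to 7.63) in the third and 21.5% (13.1 to 32.2) in the fourth. Direction taken from RPKM, which is scaled to depth, changed these shares only in the third list, to 6.87%, through 5 windows. The number of windows that pass depends on the scaling and on the test. An exact binomial test on the recovered reads with a constant approximation of the authors' scaling passed, at each list's own p limit, 76 higher and 507 lower windows in the first list, 22 and 142 in the second, 1 and 107 in the third, and 15 and 60 in the fourth. The same test scaled to column depth passed 59 higher and 578 lower in the first, 58 and 55 in the second, 4 and 47 in the third, and 17 and 36 in the fourth. The log2 fold change of the authors' deposited table differed from the log2 ratio of RPKM by a median of 0.09 in the first list, -0.53 in the second, -0.47 in the third and -0.26 in the fourth. These medians served as the approximation, but the difference was not constant. In the second list it was positive at the abundant Tmx3 window at 90771501 (log2 fold change 0.61 at 155.6 against 115.1 RPKM). In the first list it was negative at an abundant mitochondrial window (log2 fold change -0.53 at 108.6 against 111.1 RPKM). The counts that passed with the approximation are therefore not those of the authors' own scaling. The values below are RPKM, with ratios scaled to depth. The largest p-value in the authors' deposited table was 9.94e-06 in the first list, 9.89e-05 in the second, 9.22e-05 in the third and 9.01e-05 in the fourth.

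**Figure D1:**
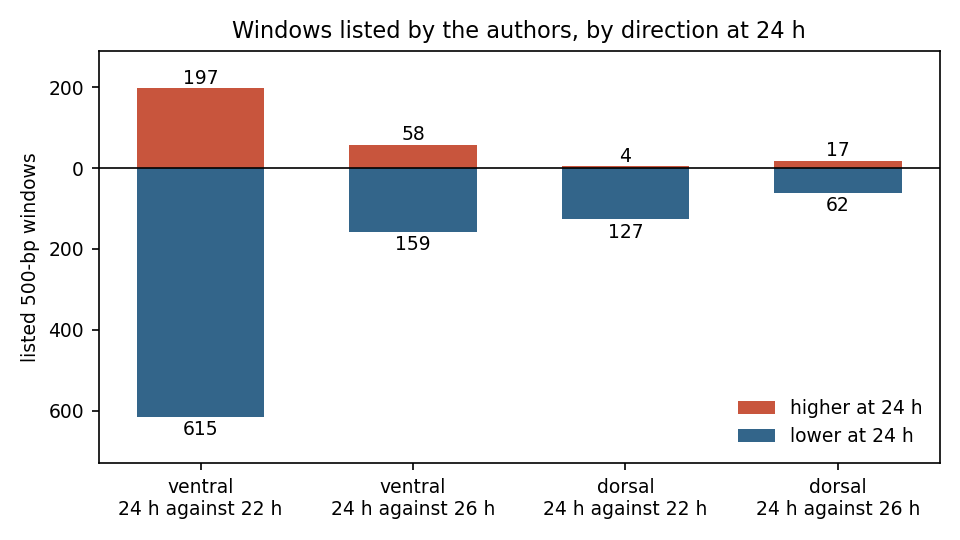
Number of 500-bp windows in each of the authors' 4 lists (vertical axis), drawn upward in red when higher at 24 h and downward in blue when lower at 24 h. The lower windows outnumber the higher ones in each list, by 615 to 197 in the ventral 24 h against 22 h list. Among the mostly unique windows of that list the order turns, with 111 higher and 18 lower.

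In the ventral SCN, most windows lower at 24 h than at 22 h lay in or near sequence with features of retrotransposons. Of the 615 windows lower at 24 h, 509 (82.8%) carried or adjoined at least 1 retrotransposon feature, against 15 of 197 windows higher at 24 h (7.61%; Fisher exact p = 4.62e-85, adjusted p = 8.32e-84) and 128 of 2000 random windows (6.4%). Among the 282 random windows that were not mostly unique, 67 (23.8%) did. The 615 lower windows had a median RPKM of 2.68 at 24 h and 14.9 at 22 h. LINE-1-type reading frames were found within 8000 bp of 345 of them (56.1%, against 4.8% of random windows), tandem units of the LINE-1 promoter type in 347 (56.4%, against 0.2%), and LTR-type frames near 141 (22.9%, against 1.5%). In random windows that were not mostly unique these shares were 17.0%, 1.06% and 6.03%. LINE-1 and LTR elements are mobile sequences that copy themselves through RNA and are held silent by methylation in most tissues.

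These lower windows were dense in CpG, a dinucleotide that is a main site of DNA methylation. Their median was 28 CpGs per window, against 5 in the windows higher at 24 h and 3 in random windows (permutation p = 1e-05 for lower against higher, the smallest that 100000 draws can give). The sequence was present in many copies: the median 31-base word occurred 781 times in the genome, and 18 of the 615 windows (2.93%) were mostly unique, against 85.9% of random windows. In the remaining windows most words occur in several copies, so for many reads the copy they came from is not known. Most of the 812 windows of the list lay between genes (559, or 68.8%) and 15 lay in a promoter.

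**Figure D2:**
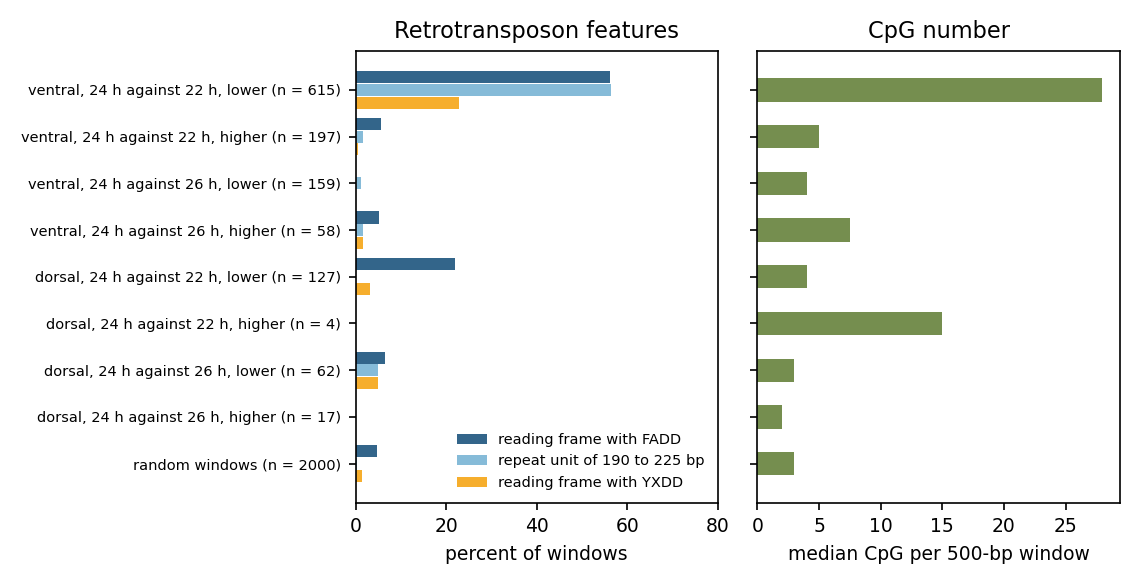
Share of windows (percent, left) with a LINE-1-type frame (FADD, dark blue), LINE-1 promoter-type tandem units (light blue) or an LTR-type frame (YXDD, yellow), and median CpG number per 500-bp window (right), for the windows lower or higher at 24 h in each list and for 2000 random windows. The ventral windows lower at 24 h than at 22 h stand apart, with 56.1%, 56.4% and 22.9% for the features and a median of 28 CpGs.

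The individual windows with the largest deficits at ventral 24 h had no reads in that column. The largest was nearest the predicted gene Gm19757 on chromosome 6 (105441501 to 105442000), with 0 RPKM at 24 h and 13.2 at 22 h, at least 11.5-fold lower. The window nearest Mast4, a microtubule-associated kinase gene, on chromosome 13 (104191001 to 104191500, mm9) had 0 RPKM at 24 h and 8.81 at 22 h, at least 7.68-fold lower. A window nearest Lama2, which encodes a laminin chain of the extracellular matrix, had 0 against 6.12 RPKM (at least 5.34-fold lower), and a window called promoter at Wapal, a regulator of cohesin release from chromosomes, had 0 against 7.59 (at least 6.62-fold lower). The Wapal window lay 35.6 kb from the start site that the authors give. Dsel, Api5, Triqk, Hnf4g and Ccdc71l were the nearest genes to further windows of this kind, at least 7.25-, 7.04-, 6.62-, 5.97- and 5.34-fold lower.

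Among the fixed gene groups, synaptic and neural cell adhesion stood out in this comparison. Windows of the list were named after 16 of its 83 members in the annotation (odds ratio 14.2, Fisher exact p = 6.85e-13, adjusted p = 4.38e-11), with 18 of 20 windows lower at 24 h. A window nearest Cdh11, a cadherin, had 0.76 RPKM at 24 h and 11.5 at 22 h (15-fold lower, 95% interval 3.94 to 128). It lay 819 kb from the Cdh11 start site, and the Ncam2 window named next lay 165 kb from that of Ncam2. A window nearest Ncam2, a neural cell adhesion molecule, had 1.53 against 16.7 RPKM (10.9-fold lower, 4.06 to 41.1), and intronic windows of Nrxn3 and Cntnap2, members of the neurexin family of synaptic organisers, were 8.75-fold (2.79 to 44.2) and 5.58-fold lower (2.55 to 14.5). Chl1, Lrfn5 and Cntnap5a also held the window in an intron. Ptprd, a receptor tyrosine phosphatase of synapses, went the other way, with 7.26 RPKM at 24 h and 0.49 at 22 h in an intron (14.8-fold higher, 3.58 to 131). Of the 20 windows, 16 carried or adjoined retrotransposon features, and 8 lay in the named gene or its promoter. Adhesion genes are long and lie in wide gene-poor regions: random genes matched on length gave a mean of 6.61 members (adjusted p = 0.0512, random draws), and random genomic windows named after their nearest start site gave a mean of 19.6 members, above the observed 16.

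Neurotransmitter genes gave fewer windows. GABA, the main transmitter of SCN neurons, was represented by 3 of 47 members, all lower at 24 h (Fisher exact p = 0.0453, adjusted p = 0.58). An intronic window of the GABA-A receptor subunit Gabrg3 had 0.76 RPKM at 24 h and 8.32 at 22 h (10.9-fold lower, 2.79 to 93.5), and the window nearest Gabrq was 5.38-fold lower (2.78 to 11.6). In the glutamate group, 2 of 43 members had 4 windows, all lower: an intronic window of the postsynaptic scaffold Dlg2 was 3.4-fold lower (1.98 to 6.22) and 3 windows nearest the AMPA receptor subunit Gria3 were between 4.85- and 8.54-fold lower (Fisher exact adjusted p = 0.812 for the group). Of the ion channels, the window nearest the potassium channel Kcnj6 was 7.68-fold lower (2.81 to 29.3; 1 of 87 members, Fisher exact adjusted p = 1).

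Clock and developmental genes also had few windows. Of 30 clock genes in the annotation, Nr1d2, a repressor of the core clock loop, was the nearest gene of a window 93.9 kb from its start site, 6.88-fold lower at 24 h (2.5 to 26.4; Fisher exact adjusted p = 1). Of 48 neuropeptide genes, Npy2r, a neuropeptide Y receptor, was the nearest gene of a window with the same values, 46.2 kb from its start site (Fisher exact adjusted p = 1). Transcription factors of hypothalamic development were the nearest genes of 5 windows for 4 of 56 members, all lower at 24 h (Fisher exact p = 0.015, adjusted p = 0.24), among them Sim1, with 1.15 RPKM at 24 h and 11 at 22 h (9.6-fold lower, 3.08 to 48.3), Tcf7l2, Meis1 and Pou3f4. Their distances from the start sites ran from 66.4 kb (Pou3f4) to 395 kb (Meis1), with 139 kb at Sim1. The windows nearest Slit2 and Robo2, an axon guidance ligand and its receptor, were 6.4-fold (2.57 to 20.6) and 4.35-fold lower (2.23 to 9.48), while that nearest the netrin receptor Dcc was 2.99-fold higher (2.06 to 4.38; 3 of 72 members, Fisher exact adjusted p = 0.717). The imprinted genes Snrpn and Peg10 (2 of 50; Fisher exact adjusted p = 0.95) and the neuronal marker Elavl2 (1 of 19; Fisher exact adjusted p = 1) were each the nearest gene of a window lower at 24 h. All 3 windows lay between genes, at 630, 67.4 and 241 kb from the start sites in that order. All windows near clock, neuropeptide, GABA, glutamate, ion channel, transcription factor and neuronal genes carried or adjoined retrotransposon features.

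The 197 windows higher at ventral 24 h than at 22 h were of another kind. Their median RPKM was 10.7 at 24 h and 2.94 at 22 h, 111 of them were mostly unique, and 83 (42.1%) held short tandem repeats, against 15 of the 615 lower windows (Fisher exact p = 1.39e-42, adjusted p = 1.50e-41) and 0.4% of random windows. The largest differences were nearest Tmem121, with 10.7 RPKM at 24 h and 0 at 22 h on chromosome 12 (114463501 to 114464000; at least 14.6-fold higher), and at windows nearest Gli2, a transcription factor of hedgehog signalling (20.3-fold higher, 3.05 to 863), Frk, a Src-family kinase (21.9-fold, 3.33 to 925), Adam18 (25-fold, 3.88 to 1050) and Ppp2r1b (5.35 against 0 RPKM, at least 7.29-fold). The Tmem121 window held 0 CpGs and was not mostly unique. It lay 39.6 kb from the Tmem121 start site, and the Frk window lay 565 kb from that of Frk. Light input and second-messenger genes had 2 of 61 members here, both higher in introns: the calcium-sensitive adenylyl cyclase Adcy8, with 8.41 against 1.71 RPKM (4.91-fold, 2.03 to 13.6), and the calcium release channel Itpr2, with 13.4 against 4.41 (3.04-fold, 1.67 to 5.7; Fisher exact adjusted p = 1).

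In the ventral SCN after 26 h cycles, the listed DNA was different. Of the 217 windows, 73 (33.6%) lay in promoters, against 4.15% of random windows. Of these 73, 16 were windows of the mitochondrial chromosome and 36 belonged to the stretch described next, leaving 21 elsewhere. Retrotransposon features marked 6 of the 217 (2.76%). A stretch of chromosome 11 around Sfi1, a centrosomal protein gene, and the pseudogene Pisd-ps3 held 51 windows nearest Sfi1 and 29 nearest Pisd-ps3 between 3027001 and 3097000, of which 1 was higher at 24 h. Their median RPKM was 3.82 at 24 h and 12.1 at 26 h near Sfi1, and 3.06 against 9.75 near Pisd-ps3. Within this stretch, a window called promoter at Sfi1 (3076001 to 3076500) had 2.68 RPKM at 24 h and 15.7 at 26 h (5.86-fold lower, 2.71 to 15.1). It lay 17.2 kb from the start site that the authors give. Mostly unique in mm9 were 50 of the 51 windows and 25 of the 29. Chromosome 11 as a whole held 85 of the 201 nuclear windows, against 9.22 expected from its length. Of the windows lower at 24 h, 10 had no reads in that column. The largest deficits among them were nearest the predicted gene Gm21119, with 5.09 RPKM at 26 h (at least 4.44-fold lower) in a window and 4.66 (at least 4.06-fold) in another, and at 4930467E23Rik, with 4.66 (at least 4.06-fold). Others were nearest Slc16a14, a monocarboxylate transporter gene, with 3.82 (at least 3.33-fold), Obox1, a homeobox gene of oocytes, with 3.82 (at least 3.33-fold), and Dpyd, a pyrimidine-degrading enzyme, with 3.6 (at least 3.14-fold).

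Several windows were higher at ventral 24 h than at 26 h. As against 22 h, many of them held short tandem repeats: 25 of 58 (43.1%), against 0.4% of random windows. Of the 159 lower windows, 4 held them (Fisher exact p = 5.07e-13, adjusted p = 2.38e-12). An intronic window of Capn9, a calcium-dependent protease, had 8.03 RPKM at 24 h and 0.21 at 26 h on chromosome 8 (127135501 to 127136000; 37.9-fold higher, 6.09 to 1570). A window nearest Avpr1a, the receptor for the SCN neuropeptide vasopressin, had 11.5 against 1.48 RPKM (7.73-fold, 3.33 to 20.8) and was the 1 window of the neuropeptide group (Fisher exact adjusted p = 0.604). It lay outside the gene, 141 kb from its start site, and was not mostly unique. A window called promoter at Drosha, which starts microRNA processing, had 7.65 against 0.64 (12-fold, 3.57 to 63.2). It lay 9.68 kb from the start site that the authors give. Ion channels had 2 of 87 members, both higher: Nalcn, the sodium leak channel that sets the resting excitability of clock neurons, had 5.74 RPKM at 24 h and 0 at 26 h in an intron (at least 9.03-fold), and the window nearest Kcnh5 had 116 against 67.2 (1.73-fold, 1.47 to 2.03; Fisher exact adjusted p = 0.195). The adhesion genes Ncam2 (12-fold, 3.57 to 63.2) and Chl1 (1.78-fold, 1.53 to 2.07) were also higher (Fisher exact adjusted p = 0.195). At both, the windows listed against 22 h were other windows and were lower at 24 h. Further windows, each with 0.21 RPKM (1 read) at 26 h, lay within Col5a1, Frmd4a and Alpk1 and nearest Tex2 and Gng13, between 25.2- and 27.1-fold higher. Folds against 1 read have wide intervals and cannot be set beside bounds against the floor of 3 reads, as for Nalcn. Across the 58 higher windows the median RPKM was 114 at 24 h and 72.2 at 26 h, and the median ratio of reads was 0.998 where the ratio of depths was 0.554. At the median, the shallower column thus held about as many reads as the deeper one.

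DNA that matches the mitochondrial genome was lower at 24 h in the ventral comparison with 26 h and in both dorsal comparisons. Listed in ventral 24 h against 26 h and in dorsal 24 h against 22 h were 11 windows nearest Col19a1, a collagen gene, on chromosome 1 (24618001 to 24623500) and 6 windows nearest Gad2, a GABA-synthesising enzyme, on chromosome 2 (22443001 to 22446000, within an intron of Myo3a). Of these 17 windows, 15 aligned to the mitochondrial chromosome at a median identity of 100%. The Col19a1 windows had a median of 52.8 RPKM at ventral 24 h against 117 at 26 h, and 25.3 at dorsal 24 h against 61.2 at 22 h. The Gad2 windows had medians of 27.7 against 51.7 and of 15.1 against 30.6. The ventral 24 h against 26 h list also held 16 windows of the mitochondrial chromosome itself, all lower at 24 h with medians of 119 and 207 RPKM. The dorsal 24 h against 26 h list held 2 of the Col19a1 windows, with 6.98 against 21.8 and 38.4 against 55.1 RPKM. The ventral 24 h against 22 h list held 1 window of the mitochondrial chromosome, with nearly equal RPKM (109 at 24 h and 111 at 22 h). The dorsal lists named no window of that chromosome.

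**Figure D3:**
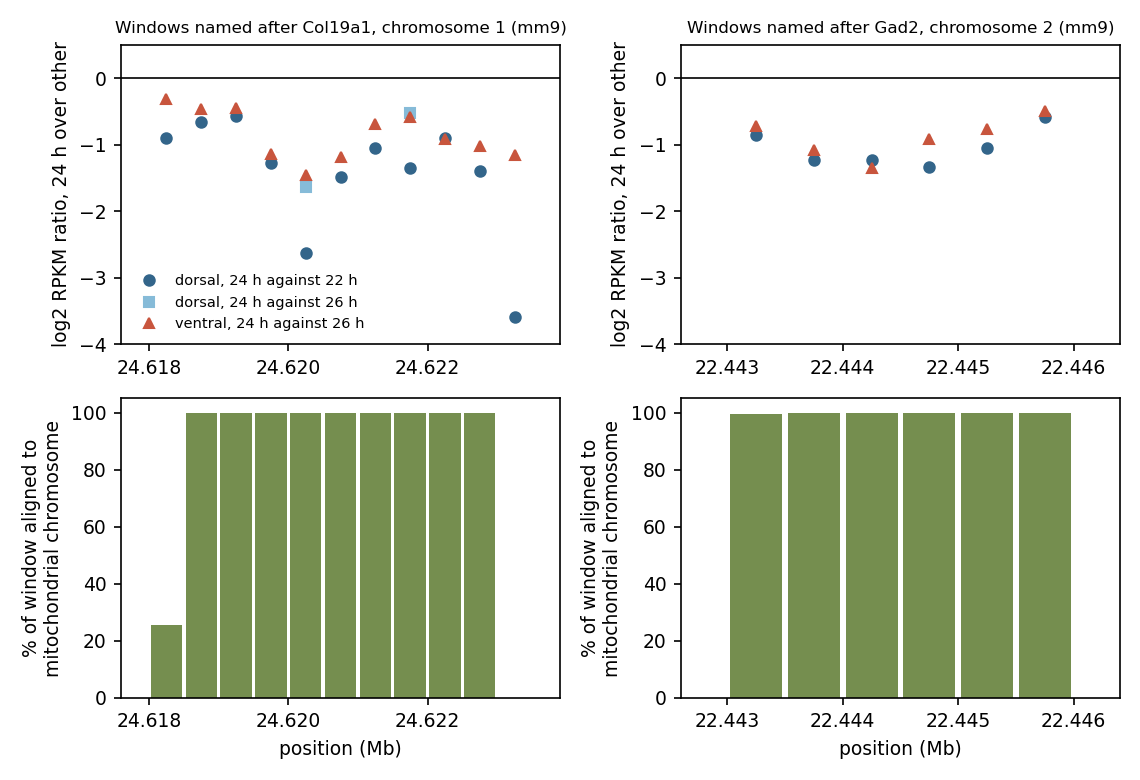
Upper panels show the log2 ratio of RPKM at 24 h over the other cycle length for each listed window nearest Col19a1 (left) and Gad2 (right) by position in Mb, with a symbol per list. Lower panels show the percentage of each 500-bp window that aligns to the mitochondrial chromosome: all points lie below 0, and 15 of the 17 windows match that chromosome.

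In the dorsal SCN, 127 of 131 windows were lower at 24 h than at 22 h, with median RPKM 1.75 and 9.09. The 4 higher windows were nearest Cartpt, a neuropeptide precursor (69.4 RPKM at 24 h, 30.1 at 22 h; 2.31-fold, 1.77 to 3.04), Itgad, an integrin (2.52-fold, 1.79 to 3.59), Ntan1 (2.75-fold, 1.87 to 4.1) and Trpc7, a cation channel, with 8.73 against 0.35 RPKM on chromosome 13 (57416001 to 57416500; 25-fold, 3.99 to 1040). Windows with 0 RPKM at 24 h lay in introns of Rims1, a presynaptic release protein (4.89 at 22 h, at least 3.73-fold lower), and Acsl6, a fatty acid-CoA ligase (7.34, at least 5.61-fold), and nearest 4930467E23Rik (8.39, at least 6.41-fold), Cenpw, a centromere protein (6.29, at least 4.8-fold), Fbln5 (7.69, at least 5.87-fold) and Fbxo8 (6.29, at least 4.8-fold). The Acsl6, Fbln5 and 4930467E23Rik windows held 0 CpGs, and the Rims1 and Cenpw windows held 1 each. Short tandem repeats were present in 3 of the 4 higher windows and 25 of the 127 lower ones (19.7%), against 0.4% of random windows. The Cartpt, Acsl6 and Fbln5 windows were among these and were not mostly unique. LINE-1-type frames adjoined 28 of the 127 lower windows (22.1%, against 4.8% of random windows). Of these 127, only 40 were mostly unique, and random windows that were not mostly unique had such frames in 17.0%. An intronic window of the adhesion gene Lsamp was 3.6-fold lower (1.46 to 10.7; 1 of 83 members, Fisher exact adjusted p = 0.775), and Gad2 was the 1 GABA member (Fisher exact adjusted p = 0.604). In 5 windows the authors' direction was lower while RPKM was higher at 24 h.

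After 26 h cycles, dorsal windows again were mostly lower at 24 h, 62 of 79, with median RPKM 1.31 and 13. Among the largest deficits were a window nearest the heparan sulfate enzyme gene Ndst4, with 0.44 RPKM at 24 h and 12.5 at 26 h on chromosome 3 (124931001 to 124931500; 28.6-fold lower, 4.81 to 1160), 1 nearest the olfactory receptor gene Olfr854 (23.4-fold, 6.2 to 198), and an intronic window of Myo7a, an unconventional myosin (20.6-fold, 5.44 to 175). A window nearest 3110007F17Rik had 0 against 7.62 RPKM (at least 5.82-fold lower). The window nearest Mab21l1, in the promoter of Nbea, had 0 against 6.24 RPKM (at least 4.77-fold lower). The calcium-activated chloride channel gene Ano2 held 2 intronic windows, 6.24-fold (2.83 to 16.2) and 4.65-fold lower (2.07 to 12.3; 1 of 87 ion channel genes, Fisher exact adjusted p = 0.717). Higher at 24 h were intronic windows of Rcan1, an inhibitor of calcineurin (7.86 against 0.35 RPKM; 22.7-fold, 3.58 to 944), of Gria1, an AMPA receptor subunit (11.4 against 1.73; 6.55-fold, 2.47 to 21.8; 1 of 43 glutamate genes, Fisher exact adjusted p = 0.604), and of Lpar3, a lysophosphatidic acid receptor (5.14-fold, 2.7 to 10.6), and windows nearest Twist2 (21.4-fold, 3.35 to 895) and Lsm6 (6.3-fold, 2.58 to 18.5). Short tandem repeats were present in 11 of the 17 higher windows and 12 of the 62 lower ones, the Gria1 window among the former. The Ndst4, Myo7a and Gria1 windows held 0 CpGs, and the other windows named here for this list held 1 to 7.

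In the 4 lists, no window was named after a gene of the DNA methylation machinery or after a marker of astrocytes, oligodendrocytes, microglia or vascular and meningeal cells. Clock genes had no window outside the ventral 24 h against 22 h list.

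Lists with a common 24 h column were compared within each part, and a common direction of their shared windows goes with that column and was not tested. The dorsal lists shared 26 windows, all lower at 24 h against 22 h and against 26 h, and 15 genes, among them Rims1, Cenpw, Myo7a, Olfr854, Cyr61 and Tbl1xr1, a transcriptional corepressor subunit. Of these windows, 18 were mostly unique. Tmx3, a gene of the thioredoxin family, was named in all 4 lists, and its tandem-repeat window on chromosome 18 (90772001 to 90772500) had 6.98 RPKM at dorsal 24 h, 61.9 at 22 h (8.86-fold, 5.31 to 15.8) and 38.8 at 26 h (5.56-fold, 3.28 to 10.1). Were the 26 h column no different from the 22 h column, simulated reads would have given a mean of 13 shared windows from the common 24 h column (95% range 9.98 to 17), and a mean of 6.48 shared genes (4 to 9). The ventral lists shared 4 windows, all in the same direction: those nearest Tmem121, Hsd17b13 and C1qtnf9 were higher at 24 h and a mitochondrial window was lower. The Tmem121 and Hsd17b13 windows held 0 CpGs, and the C1qtnf9 and mitochondrial windows held 9 each. The same simulation gave 207 shared windows (188 to 228), far above the 4 observed. The ventral lists had 13 genes in common, mostly through different windows, where the simulation gave 162 (145 to 180).

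Ventral and dorsal lists shared few windows at matched cycle lengths. The Fisher test of shared genes takes no account of gene length or of naming after the nearest start site. At 22 h they shared 0 windows and 5 genes (Fisher exact p = 0.00461), and with protein-coding genes only they shared 3 genes (Fisher exact p = 0.14). At 26 h they shared 5 windows (13 of the 217 ventral windows lay within 1000 bp of a dorsal one and 33 within 10000 bp), 2 in the same and 3 in the opposite direction (exact binomial p = 1), and 4 genes (Fisher exact p = 1.45e-06). Were all windows of the genome equally likely to be listed, chance would give at most 0.0153 shared windows in a direction at 22 h and 0.00193 at 26 h. Many listed windows were multi-copy, and 1 of the 5 windows shared at 26 h was mostly unique, so these values are likely too low. Across cycle lengths, the ventral 24 h against 26 h list shared 24 windows with the dorsal 24 h against 22 h list, of which 17 were the Col19a1 and Gad2 windows. The ventral 24 h against 22 h list shared 3 with the dorsal 24 h against 26 h list. These were nearest Gm597, Kit, a receptor tyrosine kinase, and Mir7087, genes chosen after their values were seen, and were higher at 24 h in both.

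Windows were unevenly spread over the chromosomes. The X chromosome held 75 ventral windows of the 22 h comparison, against 50.9 expected from its length (permutation p = 0.00134 over all chromosomes). The spread was also uneven for ventral 24 h against 26 h (permutation p = 1e-05, the smallest the draws can give) and dorsal 24 h against 22 h (permutation p = 0.00432), but not beyond chance for dorsal 24 h against 26 h (permutation p = 0.0645). With neighbouring windows merged, the dorsal 24 h against 22 h value was p = 0.56 by the same permutation test. No listed window lay on the Y chromosome.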

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

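Chosen after the results were seen were the binomial tests on recovered reads list by list, the CpG tests in the ventral 26 h list and in the dorsal lists, and all tests of the retrotransposon windows, where loss of multi-copy reads was tested in 4 forms and CpG-dense capture in 2. A trio of windows had opposite directions in the ventral and dorsal comparisons of 24 h with 26 h, and the difference between the parts was not tested. The log2 fold change in the authors' deposited table was 0.61 in the ventral and -0.84 in the dorsal part at the window nearest Tmx3 (chromosome 18, 90771501 to 90772000). It was 0.62 and -0.53 at the window nearest Gm14496, and 0.74 and -0.63 at the Sfi1 promoter window (chromosome 11, 3093001 to 3093500). The Tmx3 and Gm14496 windows held 0 CpGs, and their median 31-base words occurred 1355 and 1351 times in the genome. The Sfi1 window held 42 CpGs and was mostly unique.

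The lower values at 24 h of the windows nearest Col19a1 and Gad2 may come from reads shared with mitochondrial DNA. Of the 17 distinct windows, 15 (88.2%) aligned to the mitochondrial chromosome, the lowest identity being 95.9%, and all 36 listings were lower at 24 h. The sequence matches whatever the cause, so this shows only that reads could be shared. In ventral 24 h against 26 h, 16 of the 33 windows of the mitochondrial chromosome were listed too. In dorsal 24 h against 22 h 0 were, beside 15 matching nuclear windows. This does not go with shared reads there, though unlisted windows cannot be seen. A difference in methylation of the nuclear DNA stays open: at least 50% of the 31-base words occurred once in the genome in 1 of the 17 windows, and 14.3 to 58.9% did across the 6 Gad2 windows, where part of the reads can be placed, while 8 of the 11 Col19a1 windows had no such word. Whether the mitochondrial share of a sample followed cycle length or dissection was not tested.

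That most listed windows were lower at 24 h could come in part from depth. Scaled to depth, 716 of the 963 lower windows (74.4%) passed their list's limit: 94% in ventral 24 h against 22 h, 34.6% in ventral 24 h against 26 h, 37% in dorsal 24 h against 22 h and 58.1% in dorsal 24 h against 26 h. All had been selected from the same reads. In ventral 24 h against 22 h the authors' log2 fold changes differed from the log2 ratios of RPKM by a median of 0.09. This argues against much depth left in the fold change of a typical window of that list. At 2 abundant windows the fold change lay well below the ratio of RPKM, which leaves depth open at such windows. A mitochondrial window had -0.53 at 108.6 against 111.1 RPKM, and a window nearest Pisd-ps3 had -0.85 at 54.7 against 65.9. In the lists after that one, 151 of 159, 122 of 127 and 62 of 62 lower windows had a depth-scaled ratio with its 95% interval below 1 (medians 0.38, 0.178 and 0.12). These windows had been listed for low values at 24 h, so such intervals were nearly fixed by the selection and cannot decide about depth. Its part in the lower values and in the surplus over higher windows stays open there. The lists were drawn up with the authors' scaling, and other windows cannot be seen. More unenriched DNA in the 22 h and 26 h columns would raise windows poor in CpG, and it is excluded as the whole cause by the median of 28 CpGs in the ventral 22 h list, against 5 in the higher windows. In the ventral 26 h list and the dorsal 22 h list the lower windows did hold fewer CpGs (medians 4 against 7.5, permutation p = 2e-05, and 4 against 15, permutation p = 0.00092), which leaves it open there. In the dorsal 26 h list the test decided nothing (permutation p = 0.684). These permutations treat windows as independent, although 50 and 29 lower windows of the ventral 26 h list were nearest Sfi1 and Pisd-ps3. In the dorsal 22 h list only 4 windows were higher. The p-values may thus reflect the CpG content of a few stretches, and merged regions were not tested for them. An effect of cycle length itself was not tested, since each group is 1 column.

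The retrotransposon windows lower at ventral 24 h than at 22 h have a candidate technical explanation in stronger capture of CpG-dense DNA in the 22 h column. Among mostly unique windows without retrotransposon features, the 10 lower ones also held more CpGs than the 109 higher ones (medians 13 and 5, permutation p = 0.0124; with neighbours merged 11.5 and 5, permutation p = 0.0293). Reads of multi-copy DNA kept in the 22 h column and dropped at 24 h stay open. Of the 615 lower windows, 597 were not mostly unique, and mostly unique windows were 86.1% higher, which goes with such a loss. Among mostly unique windows 8 of 18 lower and 2 of 111 higher ones carried or adjoined these features (Fisher exact p = 1.11e-06), which goes against it, but only 54.9 to 79.6% of the words of these 8 occurred once. With at least 90% unique words, none of 3 lower and 55 higher windows had the features. That test (Fisher exact p = 1) could not decide either way, because no window had them. Higher methylation of retrotransposons after 22 h days stays open as a hypothesis. In the list of ventral 24 h against 26 h, which uses the 24 h column again, 2 of 159 lower windows carried or adjoined these features, so the difference was not seen against 26 h, but with 1 column per group a difference between mice and one between captures or alignments cannot be told apart.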

How the results depend on the processing

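Of 126 alternatives, 72 were planned; added after seeing the data were the equal p limit of 1e-05, mostly unique windows, the binomial test on recovered reads with either scaling, direction from RPKM, random windows as background for the gene lists, and merged windows for the chromosome test. Direction and side of the threshold, or a count within 1.5 times, held in 77 of them; 41 values moved, 2 reversed, 5 became weaker and 1 stronger. No paired analysis was possible because each group is 1 column, and the planned leave-one-out, replicate block, DESeq2 and low-value filter alternatives were not run for that reason. A shared length of 50% is void on a fixed window grid. Depth limits small changes: at 2-fold, 12.5% of simulated windows were called in ventral 24 h against 22 h, 49.1% against 26 h, and 32.3% and 23.1% in the dorsal comparisons. Unless stated, the cause of a difference was not tested.

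Comparisons follow the order ventral 24 h against 22 h and 26 h, then dorsal. With fewer windows by construction, the 10 times stricter p left 336 windows in the first, 61 in the third and 39 in the fourth, with 14.6% higher at 24 h in the first and 5.13% in the fourth. A fold change at or above the median left 408, 109, 67 and 40, with 14.9% higher in the first, 15.6% in the second and 7.5% in the fourth. At 1e-05 the dorsal lists held 61 and 40 windows, with 7.5% higher in the latter. Mostly unique windows numbered 129, 113, 41 and 50; the share higher at 24 h reversed to 86.1% in the first, where most lower windows are multi-copy, and was 17.7% in the second. The binomial test scaled to depth kept 113 windows in the second and 51 in the third, with 9.26%, 51.3% (reversed) and 7.84% higher in the first, the second and the third. With the constant approximation of the authors' scaling the same test gave 13% and 13.4% higher in the first and the second. Merging left 78 regions in the second, 44.9% of them higher, because the lower windows adjoin one another.

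The enrichment of adhesion genes in the first comparison fell from 1 list to 0 with mostly unique windows (Fisher exact adjusted p = 0.142), with random genes matched on length (adjusted p = 0.0512, random draws) and with random windows named after the nearest start site (adjusted p = 1, random draws). As many adhesion genes as observed came up in a share of 0.88 of those draws of random windows, so the naming of windows may account for this enrichment. It held with protein-coding genes, with the stricter p and with windows inside the gene or its promoter, at adjusted p between 5.56e-09 and 1.34e-05 (Fisher exact).

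Ventral lists for 22 h and 26 h shared 7 windows within 10000 bp, 1 at the stricter p and 1 mostly unique window. Dorsal lists shared 14 at the stricter p. Ventral and dorsal lists shared 1 window within 1000 bp and 2 within 10000 bp at 22 h, and 3 protein-coding genes (Fisher exact p = 0.14). At 26 h they shared 13 within 1000 bp, 33 within 10000 bp, 3 at the stricter p and 1 mostly unique window. The uneven spread over chromosomes was lost in the third comparison with merged windows (permutation p = 0.56), and in the fourth it passed when expected from gene numbers (permutation p = 0.0141).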

Other observations

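Beyond the gene lists, several groups of windows with the same nearest gene stood out. In the ventral comparison of 24 h with 26 h, 9 windows nearest B020014A21Rik on chromosome 10, 7 nearest Lrrc4c on chromosome 2 and 4 nearest Tmem125 on chromosome 4 were higher at 24 h, with medians of 133, 175 and 261 RPKM at 24 h against 90.3, 104 and 145 at 26 h. Lrrc4c encodes a synaptic adhesion protein, but its windows lay in or near the predicted genes Gm10800 and Gm10801. In the ventral comparison with 22 h, 5 windows each nearest Hs3st5, Map3k7 and Nudt12 were lower at 24 h, with medians of 27 to 31 CpGs. In the dorsal comparison with 22 h, 5 windows nearest 1700080N15Rik on chromosome 2 had a median of 0 RPKM at 24 h and 6.64 at 22 h with a median of 0 CpGs, and 7 windows nearest G530011O06Rik on the X chromosome had 9.6 against 30.8 RPKM. The windows nearest Hs3st5, Nudt12 and G530011O06Rik do not all lie close together. These groups were chosen after their values were seen.

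The ventral 24 h against 26 h table held 220 entries for 217 windows. Of the 3 windows with a pair of entries, a pair with the same start position on chromosomes 11 and 17 (3081501) was entered under both Pisd-ps2 and Sfi1, so that each window was once joined to a gene of the other chromosome. The third was a mitochondrial window named once after Dhrsx. Each was counted once.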
